A study of Mus musculus with 8 samples.

How the data were processed

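Kidney RNA from 8 male mice was measured by bulk RNA sequencing. All were knock-in mice of a model of MUC1 kidney disease, an inherited tubulointerstitial disease in which a frameshift in MUC1 yields an abnormal secretory-pathway protein. They were 8 months old. Per the labels' protocols, 4 mice received vehicle (saline) and 4 received the small molecule BRD4780 at 50 mg/kg, every day for 7 days. The titles of the treated samples name the treatment AGN50 instead, and groups were taken from the treatment label. RNA was taken from a sagittal slice of the kidney, and mRNA was captured on oligo-dT beads with an automated stranded TruSeq protocol. The design text gives 4 mice per arm, so each library stands for a separate animal. Libraries are named here by treatment and a replicate number that follows the order of deposition and pairs nothing.

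The deposited values are estimated read counts per gene (expected counts), not normalized, in which 15.1% to 28.9% of the values of a library were not whole numbers. Per the submitters' processing notes, the tools named are STAR 2.5.2b, RSEM 1.3.0 and Picard, and the genome builds named are mm10 and hg19, with no role stated for either build. The annotation, the read filters and the strand setting of the counting are not given in the sources used here. RSEM shares reads that fit several genes among them by likelihood, so values of near-identical genes, such as Cyp4a12a and its neighbour, the Ugt1a cluster, histone genes, hemoglobin genes and ribosomal protein genes with pseudogenes, are less certain than others. Reads of overlapping genes on opposite strands can be told apart only if strand was used in counting. Of the 160 genes named by the rule below, 41 had exons overlapping a gene on the opposite strand and 16 on the same strand in GENCODE M21.

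The table held 22121 entries. A set of 343 gene symbols stood on more than 1 line with identical values and was collapsed, which left 21759 genes. The table had 1 column of per-sample values that matched none of the samples analysed, and it was not used. Of 22116 Ensembl identifiers, 21790 were found in GENCODE M21, from which coordinates on GRCm38 (mm10), transcript length and GC content were taken. Genes encoded by the mitochondrial genome were not analysed here. Totals ranged from 16.6 to 28.5 M counts in the vehicle group and from 5.74 to 28.2 M in the BRD4780 group. No 2 libraries were alike within sampling noise, since the lowest chi-square per degree of freedom between any pair was 7.98. A count of 0 allows up to 3 counts, which is 0.105 CPM in vehicle replicate 1, the deepest library, and 0.523 CPM in BRD4780 replicate 4, the shallowest. Such floors, and the counting interval given for Fgf21 (95%, exact binomial), cover counting error only.

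Expected counts were rounded to whole numbers. Genes were kept with filterByExpr (minimum count 10) and normalized by TMM in edgeR 4.0.16 under R 4.3.3. The quasi-likelihood F-test compared BRD4780 with vehicle over all 8 libraries with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over 13474 genes with a threshold of 0.05. Adjusted p-values of genes come from this test unless another is named. Log2 fold changes are BRD4780 over vehicle. Their standard error is the absolute log2 fold change divided by the square root of F. Values per library are counts per M (CPM) with TMM-scaled totals, given as mean ± SD.

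Before the data were examined, 40 gene lists were fixed for folding and secretion, stress responses, kidney and other cell types and metabolism, together with the tests, the alternatives and the rule for named genes. Of these lists 39 had at least 3 tested members. Each was compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over 39 lists. Camera with an estimated correlation and fry were run beside it. Numbers of changed members are given over all genes tested and adjusted over the list alone. The named genes are Muc1, Tmed9 and Nisch, the 12 largest increases and 12 largest decreases among genes past the threshold with a mean log2 CPM of at least 1, non-overlapping groups and an established symbol, and from each list past the camera threshold or with a changed member the 4 members with the smallest p (2 from other lists). Genes outside this rule are marked as chosen after their values were seen. A further gene under the rule is not reported here. Principal components were computed on log2 CPM of the 1000 most variable genes, with an exact two-sided permutation of group labels over 70 arrangements.

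The test was tried on simulated counts with the means, totals and dispersion of this comparison and 200 changed genes among 13361 tested. It called 42% of genes changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 8 false calls among 173. The changed genes were drawn from well-counted genes only, so these shares do not hold for genes with few counts. Of 99 unchanged lists 0 passed camera. Genes were simulated independently, whereas the estimated correlation within the real lists reached 0.79 (ribosomal proteins). The simulation therefore cannot show how often real lists pass camera by chance.

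Alternatives fixed beforehand were RLE and upper-quartile normalization, DESeq2 1.42.0, limma-voom with and without sample quality weights, other filters on low counts, unrounded counts, leaving out each library, the number in the sample titles as a block, 1 surrogate variable from sva 3.50.0, and other thresholds. Alternatives chosen after seeing the data were thinning every library to the shallowest total, leaving out BRD4780 replicates 3 and 4 together, and removing each library's trend with GC content and transcript length by splines. Figures were drawn with matplotlib 3.10.9.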

Results

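Bulk RNA sequencing was used to ask how the kidney transcriptome of a mouse model of MUC1 kidney disease responds to BRD4780, a small molecule described as acting on the cargo receptor TMED9 of the early secretory pathway. The comparison set 4 mice given BRD4780 at 50 mg/kg daily for 7 days against 4 given vehicle. Library totals in the vehicle group were 28.5, 28.1, 16.6 and 23.8 M expected counts for replicates 1 to 4. In the BRD4780 group they were 23.2, 28.2, 27.8 and 5.74 M.

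With BRD4780, 11 of 25 genes of the integrated stress response rose. So did 7 of 27 components of the vesicles that carry cargo between the endoplasmic reticulum (ER) and the Golgi. In the list of 23 ER chaperone and folding genes, which includes regulators, 2 fell, Pdia4 and the transcription factor gene Xbp1. As sets, these lists passed camera with a preset correlation and not with an estimated one (adjusted p = 0.46, 0.46 and 0.56). The transcription factor gene Atf5, which is in none of these lists, rose from 15.4 ± 1.6 to 110.0 ± 42.2 CPM (SD, n = 4 per group; 7.11-fold, adjusted p = 0.00207). Kdelr3, which encodes a receptor that returns escaped ER proteins, rose 4.65-fold from 1.73 ± 0.25 to 8.19 ± 1.91 CPM (SD, n = 4 per group; adjusted p = 0.00197). Of the markers of podocytes 4 of 13 rose, among them Nphs1 (nephrin, of the slit diaphragm) at 4.08-fold (adjusted p = 0.0114), and of those of endothelium 4 of 16, with both list calls lost with an estimated correlation (adjusted p = 0.46). In the other direction, Cish, a feedback inhibitor of cytokine signalling through STAT5, fell from 71.7 ± 21.4 to 16.3 ± 6.7 CPM (SD, n = 4 per group; adjusted p = 0.0107), and Kcnj1, the potassium channel ROMK of the thick ascending limb, fell from 205.9 ± 26.8 to 120.5 ± 13.9 CPM (SD, n = 4 per group; adjusted p = 0.0121). Of 13474 genes tested, 310 were higher and 84 lower with BRD4780 at an adjusted p under 0.05 by edgeR's quasi-likelihood test.

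Genes were ranked among those past the threshold with non-overlapping groups, a mean log2 CPM of at least 1 and an established symbol. The largest increase there belonged to Igfn1 (chromosome 1, 135953578 to 136006342, minus strand, mm10), a gene of an immunoglobulin-like and fibronectin-domain protein best known from muscle. It stood at 0.448 ± 0.250 CPM with vehicle and 9.66 ± 3.26 CPM with BRD4780 (SD, n = 4 per group; log2 fold change 4.44 ± 0.39 SE, adjusted p = 0.00197). Ptpn5, a tyrosine phosphatase best known from brain, followed at 21.2-fold from 0.180 ± 0.086 to 4.03 ± 2.56 CPM (SD, n = 4 per group; adjusted p = 0.0107). Gc (chromosome 5, 89417522 to 89457898, minus strand), which encodes the vitamin D-binding protein, rose 12.1-fold from 6.30 ± 2.28 to 76.29 ± 28.04 CPM (SD, n = 4 per group; adjusted p = 0.00197). Serpina6, the corticosteroid-binding globulin, rose 8.93-fold (adjusted p = 0.0223) and Hif3a, a member of the hypoxia-inducible factor family, 8.56-fold (adjusted p = 0.0156). The organic anion transporter gene Slco1a4 rose 7.57-fold and Hdc, whose product makes histamine, 6.82-fold. The kinase genes Map3k6 and Plk3 rose 5.93-fold and 5.43-fold. In all of these genes each BRD4780 library lay above each vehicle library, which the ranking required. BRD4780 replicate 3 was the lowest of the treated libraries in each.

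Decreases were smaller. After Cish (log2 fold change -2.07 ± 0.29 SE) came Fndc9 at -1.50 and Prox1, a transcription factor gene of lymphatic endothelium and tubule, at -1.43. The defensin gene Defb42 was at -1.41, the histone gene Hist2h3c1 at -1.16, and Hs6st2, a heparan sulfate sulfotransferase gene, at -1.13. Itgb6, the integrin beta 6 subunit, fell from 99.01 ± 4.04 to 50.02 ± 10.7 CPM (SD, n = 4 per group; adjusted p = 0.0114). Frzb, a secreted Wnt inhibitor gene, fell from 58.2 ± 6.9 to 28.3 ± 11.2 CPM (SD, n = 4 per group; adjusted p = 0.0409). Itih2, Ksr2, Klhl14 and Ppp1r1b completed the 12 largest decreases, at 0.460, 0.501, 0.520 and 0.520 of the vehicle level. Cish, Prox1, Klhl14 and Ppp1r1b here, and Atf5 and Plk3 among the increases, overlap annotated transcripts on the opposite strand, which matters if counting ignored strand. Hist2h3c1 shares 1825 bases with an annotated transcript on the same strand, which strand cannot separate.

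Muc1 itself (chromosome 3, 89229057 to 89233381, plus strand) gave no detectable difference, at 25.6 ± 8.8 CPM with vehicle and 28.8 ± 16.8 CPM with BRD4780 (SD, n = 4 per group; log2 fold change 0.17 ± 0.46 SE, adjusted p = 0.85). It ranged from 6.65 CPM in BRD4780 replicate 3 to 47.4 CPM in replicate 2. How far these counts include reads of the knock-in allele is not given in the sources used here. Tmed9 (chromosome 13, 55573732 to 55597697, plus strand) stood at 124.8 ± 9.2 and 140.0 ± 11.3 CPM (SD, n = 4 per group; adjusted p = 0.25) and Nisch, the gene of an imidazoline-binding protein, at 259.3 ± 15.5 and 284.9 ± 24.5 CPM (SD, n = 4 per group; adjusted p = 0.34), neither past the threshold.

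Among the targets of ATF4, the transcription factor of the integrated stress response, 11 of 25 were higher and 0 lower, and 19 were higher when adjusted over the list alone. Mthfd2, a mitochondrial folate enzyme gene, rose from 4.73 ± 0.64 to 27.7 ± 11.7 CPM (SD, n = 4 per group; adjusted p = 0.00468). Trib3, a pseudokinase gene induced by ATF4, rose 6.48-fold (adjusted p = 0.0149), the proline synthesis gene Aldh18a1 3.36-fold (adjusted p = 0.0121) and Atf4 1.52-fold (adjusted p = 0.0106). The stress hormone gene Fgf21 had 2 counts over the vehicle group and 112 over the BRD4780 group, a ratio of 61.2 with a counting interval of 16.6 to 512. The median log2 fold change of the list was 0.89. Fgf21 stays above that median even at the lower bound of its interval, so its uncertainty could not move the median. Camera gave an adjusted p of 6.91e-09, against an adjusted p = 0.46 with an estimated correlation.

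**Figure D1:**
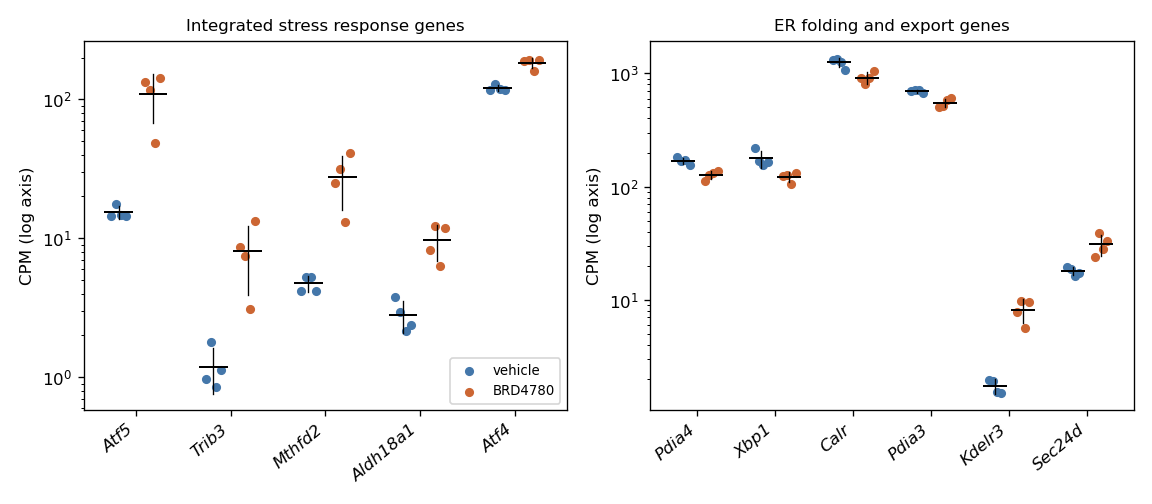
CPM on a log axis of 5 integrated stress response genes (left) and 6 genes of ER folding and export (right) in the 4 vehicle and 4 BRD4780 libraries, each point 1 library, horizontal lines the mean and vertical lines 1 SD. Atf5, on the left, is not a member of the fixed integrated stress response list. In Atf5 the treated libraries lie between 48.8 and 142.2 CPM, above the vehicle maximum of 17.7 CPM, while Pdia4 is lower in all 4 treated libraries.

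The ER chaperone and folding list went the other way. Of its 23 members 2 were lower and 0 higher, with 10 lower and 1 higher when adjusted over the list alone. Pdia4, a protein disulfide isomerase gene, fell from 169.1 ± 11.3 to 126.6 ± 11.0 CPM (SD, n = 4 per group; adjusted p = 0.0354) and Xbp1, the transcription factor gene of the unfolded protein response, from 177.2 ± 29.8 to 122.1 ± 11.3 CPM (SD, n = 4 per group; adjusted p = 0.0451). Calreticulin (Calr) had a log2 fold change of -0.45 ± 0.11 (SE) and Pdia3 of -0.34 ± 0.09 (SE), both short of the threshold over all genes (adjusted p = 0.0589 and 0.0621). The list's median was -0.18 (camera adjusted p = 0.000751, and adjusted p = 0.56 with an estimated correlation), and -0.35 without vehicle replicate 4. Its mean lay between -0.32 and -0.23 (log2 CPM relative to the vehicle mean) in BRD4780 replicates 1 to 3 and at 0.0043 in replicate 4.

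Genes of vesicle coats and cargo receptors (TMED proteins, COPI and COPII) were higher as a set, with 7 of 27 higher and 0 lower, 11 higher when adjusted over the list alone and a median log2 fold change of 0.22 (camera adjusted p = 0.00115, and adjusted p = 0.46 with an estimated correlation). Tmed3, a cargo receptor gene, rose 1.54-fold from 70.4 ± 4.0 to 108.3 ± 11.8 CPM (SD, n = 4 per group; adjusted p = 0.0121). The COPII coat genes Sec24a and Sec23a rose 1.48-fold and 1.36-fold and the COPI coat gene Copg1 1.33-fold. XBP1 targets in ER import and export had 5 of 20 members higher, over all genes and adjusted over the list alone, among them Kdelr3, the COPII genes Sec24d (1.71-fold) and Sec31a (1.28-fold) and Gfpt1 (1.46-fold), the entry enzyme of hexosamine synthesis. This list did not pass camera over all 8 libraries (adjusted p = 0.0756). Its median of 0.03 was 0.02 without vehicle replicate 2 and 0.08 without BRD4780 replicate 1, where the list passed (adjusted p = 0.0413 and 0.00364).

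Cell type markers moved apart. Podocyte markers had 4 of 13 higher and 0 lower, 10 higher when adjusted over the list alone, and a median log2 fold change of 0.94 (camera adjusted p = 2.88e-06, and adjusted p = 0.46 with an estimated correlation). Nphs1 rose from 4.80 ± 2.02 to 19.7 ± 3.7 CPM (SD, n = 4 per group), Podxl 2.52-fold, the cell cycle inhibitor gene Cdkn1c 2.93-fold and Ptpro 2.36-fold. Antisense transcripts overlap Nphs1 and Cdkn1c. Endothelial markers had 4 of 16 higher, 14 when adjusted over the list alone, and a median of 0.62 (camera adjusted p = 8.71e-08, and adjusted p = 0.46 with an estimated correlation), including the VEGF receptor gene Flt1 (1.88-fold), Robo4 (1.93-fold), Egfl7 (1.67-fold) and endoglin, Eng (1.64-fold). Exons of Egfl7 overlap annotated genes on both strands and those of Eng a gene on the opposite strand. Vehicle replicate 4 was the lowest library in both marker lists, podocyte and endothelial, with means of -0.70 and -0.45 (log2 CPM relative to the vehicle mean).

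Thick ascending limb markers had 3 of 13 lower and 0 higher, 7 lower when adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.000751, and adjusted p = 0.46 with an estimated correlation). Besides Kcnj1 these were the claudin gene Cldn19 (log2 fold change -0.92 ± 0.19 SE) and Bsnd, the chloride channel subunit barttin (-0.45 ± 0.10 SE). The mean of the list was 0.01 in BRD4780 replicate 4, inside the vehicle range, and -0.56 to -0.40 in the other treated libraries (log2 CPM relative to the vehicle mean). Markers of erythrocytes (median -1.39, 0 of 5 changed, 5 lower when adjusted over the list alone) and adipocytes (median -1.77, 0 of 8 changed either way) were lower as sets, with camera adjusted p-values of 0.00183 and 0.00125 and an adjusted p = 0.46 with an estimated correlation in both. The adipocyte median was -4.07 without BRD4780 replicate 2. Adipoq ranged from 2.19 to 16.7 CPM with vehicle and from 0.0751 to 5.03 CPM with BRD4780. Proximal tubule markers had 0 of 25 changed and a median of -0.11 (camera adjusted p = 0.0776). Without BRD4780 replicate 3 their median was -0.35 and the list passed (adjusted p = 6.11e-05).

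**Figure D2:**
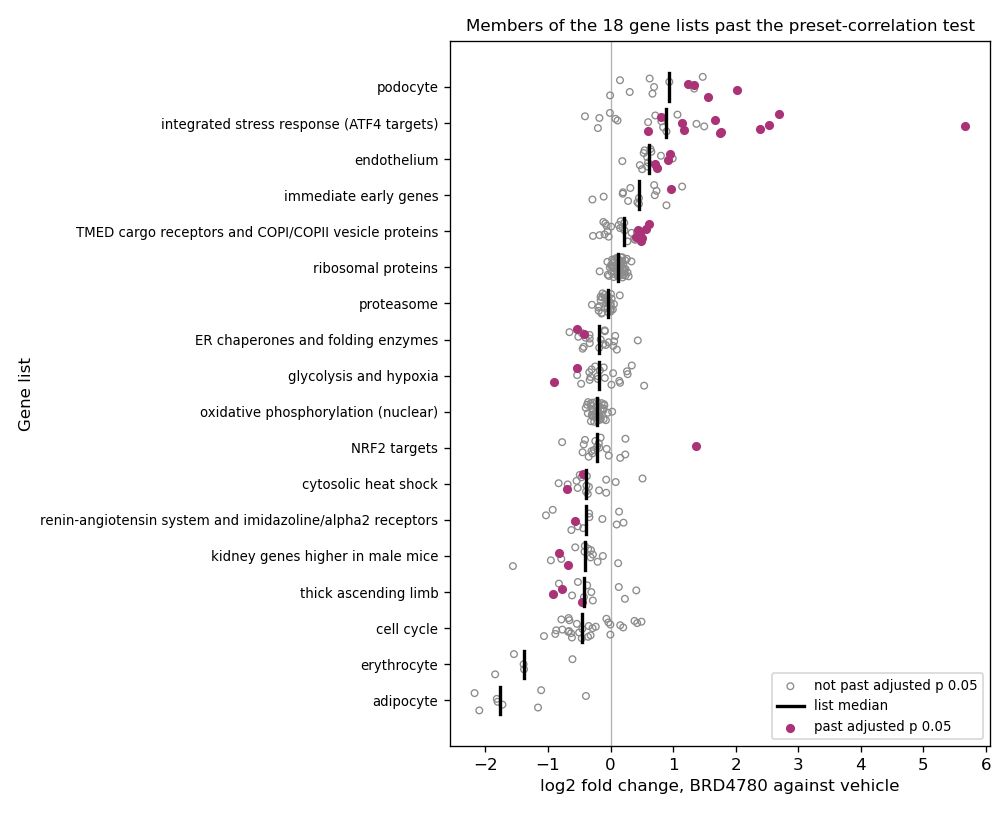
Log2 fold change (BRD4780 against vehicle) of each tested member of the 18 gene lists past camera with a preset correlation, with filled points for members past an adjusted p of 0.05, open points for the others and a bar at each list's median. Medians run from -1.77 (adipocyte) to 0.94 (podocyte), and the rightmost point, Fgf21, rests on 2 vehicle counts.

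In genes of oxidative phosphorylation encoded in the nucleus the fold change was negative in 38 of 39, with a median of -0.21, while 0 passed the gene test, also when adjusted over the list alone (camera adjusted p = 4.20e-09, and adjusted p = 0.46 with an estimated correlation). The complex I genes Ndufb8 and Ndufa9 had log2 fold changes of -0.29 ± 0.08 and -0.29 ± 0.09 (SE). Cytosolic heat shock genes had 2 of 18 lower, 10 when adjusted over the list alone (median -0.39, camera adjusted p = 4.64e-05, and adjusted p = 0.46 with an estimated correlation), namely the HSP40 gene Dnaja1 (0.620 of the vehicle level) and the co-chaperone gene Stip1 (0.739). The heat shock mean of vehicle replicate 4 (-0.40) lay below those of BRD4780 replicates 1 and 2 (-0.36 and -0.13; log2 CPM relative to the vehicle mean). Kidney genes known to be higher in male mice had 2 of 15 lower, 5 when adjusted over the list alone (median -0.41, camera adjusted p = 4.64e-05, and adjusted p = 0.46 with an estimated correlation). They were Hsd11b1, which regenerates active glucocorticoid (log2 fold change -0.82 ± 0.13 SE), and the aldo-keto reductase gene Akr1c21 (-0.68 ± 0.15 SE). The median of the kidney genes higher in male mice was -0.63 without BRD4780 replicate 3.

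Of the renin-angiotensin and imidazoline receptor list 1 of 12 was lower, 4 when adjusted over the list alone (median -0.39, camera adjusted p = 0.00542, and adjusted p = 0.46 with an estimated correlation). This was angiotensinogen (Agt), which fell from 136.2 ± 8.4 to 91.6 ± 2.9 CPM (SD, n = 4 per group; adjusted p = 0.00588). Renin (Ren1) stood at 33.0 ± 12.1 and 18.1 ± 7.6 CPM (SD, n = 4 per group; adjusted p = 0.12). Cell cycle genes were lower as a set (median -0.45, 0 of 29 changed either way, camera adjusted p = 0.000444, and adjusted p = 0.46 with an estimated correlation) from low levels, with Cenpe at 3.42 and 2.16 CPM. After thinning to equal totals the cell cycle median was -0.16 and the call was lost (adjusted p = 0.14). Among NRF2 targets the median was -0.21 (camera adjusted p = 0.0187, and adjusted p = 0.46 with an estimated correlation) with 5 of 19 lower and 2 higher when adjusted over the list alone. The 1 member past the threshold over all genes, the heme oxygenase gene Hmox1, rose 2.57-fold from 38.2 ± 9.2 to 97.8 ± 31.9 CPM (SD, n = 4 per group; adjusted p = 0.0175). Glycolysis and hypoxia genes had 2 of 22 lower, 4 when adjusted over the list alone (median -0.19, camera adjusted p = 0.0400, and adjusted p = 0.46 with an estimated correlation), carbonic anhydrase 9 (Car9, -0.91 ± 0.16 SE) and pyruvate kinase M (Pkm, -0.53 ± 0.12 SE).

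Immediate early genes had 1 of 15 higher, Klf4 at 1.96-fold (adjusted p = 0.0306), and 6 higher when adjusted over the list alone (median 0.45, camera adjusted p = 0.00184, and adjusted p = 0.47 with an estimated correlation). The mean of the list in BRD4780 replicate 3 was -0.13, inside the vehicle range of -0.19 to 0.25, against 0.56 to 0.72 in the other treated libraries (log2 CPM relative to the vehicle mean). Ribosomal protein genes (median 0.12, 0 of 54 changed) and proteasome genes (median -0.05, 0 of 31 changed) passed camera with small shifts, at adjusted p-values of 0.00607 and 0.0384 (adjusted p = 0.76 and 0.61 with an estimated correlation), and neither had a member past the threshold when adjusted over the list alone. The ribosomal call was lost without vehicle replicate 4 (median 0.08, adjusted p = 0.23) or BRD4780 replicate 2 (median 0.08, adjusted p = 0.0967), and the median of ribosomal proteins was 0.20 without BRD4780 replicate 3. The median of the proteasome list was -0.08 without vehicle replicate 3 and -0.09 without BRD4780 replicate 3. The proteasome call was lost without vehicle replicate 1 (adjusted p = 0.0542), vehicle replicate 2 (adjusted p = 0.16) or BRD4780 replicate 4 (adjusted p = 0.0743). The NRF2 call was lost without vehicle replicate 1 (adjusted p = 0.0692), and the glycolysis call without vehicle replicate 1 (adjusted p = 0.0692), vehicle replicate 2 (adjusted p = 0.0603) or BRD4780 replicate 1 (median -0.12, adjusted p = 0.0733).

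The list means of the groups overlapped in 11 of the 18 lists past camera and lay apart in 7, those of ATF4 targets, vesicle coats and cargo receptors, podocytes, endothelium, oxidative phosphorylation, glycolysis and hypoxia, and the renin-angiotensin system.

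The other lists did not pass camera. Circadian clock genes (median 0.25, adjusted p = 0.0644) had 2 of 19 higher and 1 lower, with 10 higher and 3 lower when adjusted over the list alone. Per1 and Usp2 rose 2.43-fold and 1.63-fold and the clock repressor gene Nr1d1, which overlaps Thra on the opposite strand, fell from 98.4 ± 17.2 to 61.3 ± 3.3 CPM (SD, n = 4 per group; adjusted p = 0.0217). The list passed without vehicle replicate 3 (adjusted p = 0.0202), vehicle replicate 4 (0.0361), BRD4780 replicate 1 (0.0491) or BRD4780 replicate 2 (0.0463). Among p53 targets the death receptor gene Fas (1.91-fold) and the stress cytokine gene Gdf15 (1.85-fold) rose, 2 of 17 and 5 when adjusted over the list alone (median 0.08, adjusted p = 0.11). Without vehicle replicate 2 the p53 median was 0.20 and the list passed (adjusted p = 0.0280). Tubular injury genes had 2 of 21 higher, Gdf15 and the fibrinogen gene Fga (1.86-fold), 7 when adjusted over the list alone (median 0.01, adjusted p = 0.12). That median was slightly below 0 under RLE and DESeq2 scaling (-2e-04 and -0.0045), and 0.18 without vehicle replicate 4, where the list passed (adjusted p = 0.0361). The mean of the injury list was -0.15 in BRD4780 replicate 3 and 0.22 to 0.42 in the other treated libraries (log2 CPM relative to the vehicle mean).

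Fibroblast and matrix genes had 1 of 24 higher, Sparc, a matricellular protein gene, which rose from 63.5 ± 6.5 to 110.4 ± 4.5 CPM (SD, n = 4 per group; adjusted p = 0.00249), and 2 higher when adjusted over the list alone (median -0.06, adjusted p = 0.78). Fatty acid oxidation and PPARA targets had 1 of 26 higher, the lipoprotein lipase inhibitor gene Angptl4 at 2.42-fold (adjusted p = 0.00249), with 2 higher and 1 lower when adjusted over the list alone (adjusted p = 0.63). Their median was -0.04, their mean 0.15 and the camera direction down. Gluconeogenesis and ammonia genes had 1 of 10 higher, Pck1 at 1.52-fold, with 2 higher and 1 lower when adjusted over the list alone (median 0.15, adjusted p = 0.30). Drug metabolism genes had 2 of 31 higher, Sult1a1 (2.23-fold) and Cyp2d22 (1.68-fold), with 4 higher and 2 lower when adjusted over the list alone (adjusted p = 0.38). Their median was -0.17, their mean 0.08 and the camera direction down.

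Trpm6, a magnesium channel gene, rose 1.82-fold as 1 of 14 markers of the distal convoluted and connecting tubule, 3 of which were higher when adjusted over the list alone (median 0.24, adjusted p = 0.0878). That list passed without vehicle replicate 4 (adjusted p = 0.0166) or BRD4780 replicate 2 (0.0383). Insig1, a regulator of sterol synthesis, rose 1.88-fold as 1 of 24 cholesterol synthesis genes (median -0.06, adjusted p = 0.30), and Hexa 1.29-fold as 1 of 30 lysosomal genes (median -0.05, adjusted p = 0.28), with 1 member higher in each when adjusted over the list alone. No member was past the threshold over all genes among autophagy (median -0.03, adjusted p = 0.84), interferon response (0.03 and 0.62), macrophage (-0.32 and 0.29), lymphocyte (-0.22 and 0.84), neutrophil (0.11 and 0.78), fatty acid synthesis (-0.23 and 0.12) and adrenal cortex genes (0.31 and 0.62), nor when adjusted over each list alone. Principal cell markers (-0.20 and 0.12) had 2 lower, and intercalated cell markers (-0.01 and 0.84) 2 higher and 1 lower, when adjusted over the list alone, and 0 over all genes. The principal cell list passed without BRD4780 replicate 2 (adjusted p = 0.0421) or replicate 4 (0.0435). Camera's direction was opposite to the sign of the median in the interferon (down, mean -0.07) and lymphocyte (up, mean -0.04) lists, and the mean had the other sign than the median among autophagy (0.0056) and intercalated cell genes (0.02), where camera pointed down.

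Treatment was the main axis of variation between libraries. Component 1 held 39.25% of the variance and separated the groups completely (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements can give). Vehicle libraries scored from -21.2 to -12.3, BRD4780 replicates 1, 2 and 4 from 16.8 to 32.9, and BRD4780 replicate 3 at -3.49. Component 2 held 23.87% and did not separate the groups (exact permutation p = 0.57). All 4 values of a group lay beyond all 4 of the other in 12.59% of genes (1002 higher and 695 lower), against 2.86% by chance.

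**Figure D3:**
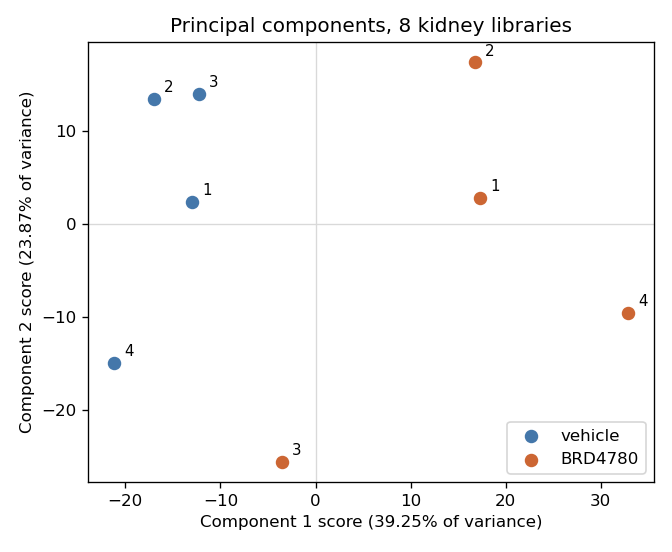
Scores of the 8 libraries on component 1 (39.25% of variance) and component 2 (23.87%), from log2 CPM of the 1000 most variable genes, with each point 1 library, its color the treatment and its digit the replicate. BRD4780 replicate 3 sits at -3.49 on component 1, between the vehicle libraries and the other treated libraries.

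The number of changed genes depended on single libraries. Without BRD4780 replicate 3 it rose to 1647 higher and 1537 lower, and all 394 genes called over 8 libraries were called there too. Leaving out another library lowered it, to 54 higher and 10 lower without vehicle replicate 1, 26 and 5 without vehicle replicate 2, 75 and 12 without vehicle replicate 3, 176 and 57 without vehicle replicate 4, 52 and 14 without BRD4780 replicate 1, 53 and 13 without BRD4780 replicate 2, and 66 and 17 without BRD4780 replicate 4. The share of increases fell from 310 of 394 to 51.7% without BRD4780 replicate 3.

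**Figure D4:**
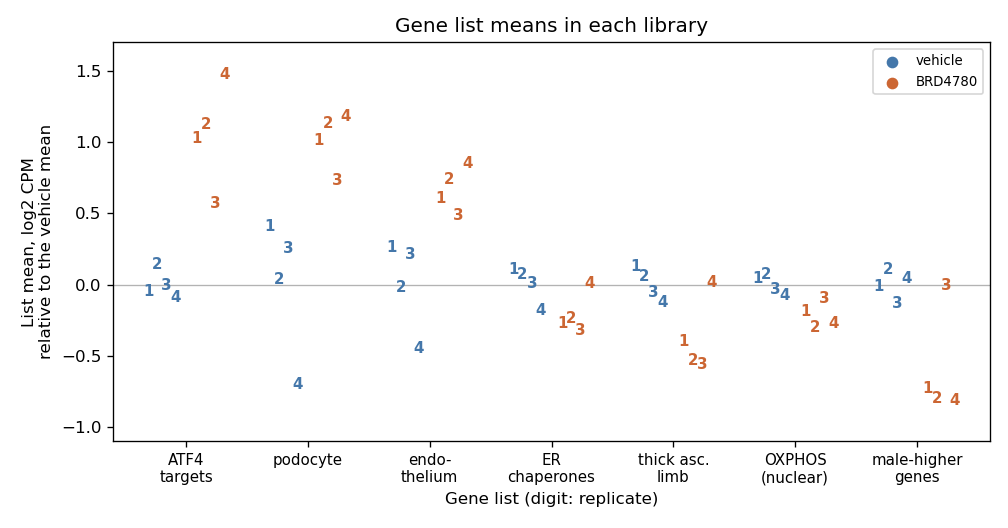
Mean log2 CPM of 7 gene lists in each library relative to the vehicle mean, with digits for replicates and colors for treatment. In the male-higher genes BRD4780 replicate 3 is at -0.0074 and the other treated libraries lie between -0.81 and -0.73.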

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

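The tests of a mislabelled library and of library depth, and the thinning, were chosen only after the result was seen. Within each group of 4 libraries, a library was singled out when its gap to the nearest other exceeded Dixon's 95% critical value as a share of the group's range. For named genes this share, the gap ratio, was taken on log2 CPM, while the values printed beside it are CPM. The ratio can therefore not be recomputed from those CPM values directly. Of 398 groups of 4 tested (library totals, list means and named genes), 23 were singled out, and chance alone singles out about 1 in 20, or 19.9. BRD4780 replicate 3 accounted for 12 of the 23. Its list means stood apart for proximal tubule markers (0.27 against -0.35 to -0.27 in the other treated libraries, gap ratio 0.874), intercalated cell markers (-0.16 against 0.06 to 0.07, ratio 0.940), ribosomal proteins (-0.14 against 0.18 to 0.24, ratio 0.847) and genes higher in male kidney (-0.0074 against -0.81 to -0.73, ratio 0.901).

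In BRD4780 replicate 3 Frzb was at 45.1 CPM against 21.9 to 23.8 CPM in the other treated libraries (ratio 0.886), Fgf21 at 0.451 against 1.61 to 2.01 CPM (0.847), Atf4 at 159.4 against 189.5 to 191.8 CPM (0.937) and Hspa8 at 4012 against 2711 to 2887 CPM (0.839). Gclm was at 248.5 against 196.4 to 203.9 CPM (0.839) and Cyp2d22 at 51.9 against 76.6 to 82.2 CPM (0.848). The ribosomal protein genes Rpl12 (313.4 against 446.1 to 471.9 CPM, 0.863) and Rpl23 (466.8 against 677.2 to 723.5 CPM, 0.849) were lower there too.

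Among vehicle libraries, replicate 4 stood apart for the macrophage gene Cx3cr1 (6.43 against 2.06 to 2.23 CPM, ratio 0.934), the collecting duct gene Fxyd4 (44.8 against 78.2 to 82.0 CPM, 0.920), Aqp3 (165.3 against 159.7 to 160.5 CPM, 0.854) and the podocyte gene Cdkn1c (3.06 against 7.99 to 8.76 CPM, 0.912). Replicate 2 stood apart for the fatty acid synthesis mean (0.27 against -0.11 to -0.07, 0.909), Atf5 (17.7 against 14.4 to 14.8 CPM, 0.866), Psmb3 (193.8 against 175.0 to 176.2 CPM, 0.933) and Car9 (124.9 against 83.9 to 89.8 CPM, 0.831). Replicate 3 did so for Hist2h3c1 (10.4 against 6.71 to 6.86 CPM, 0.952) and Cry1 (7.37 against 3.28 to 3.75 CPM, 0.835), and replicate 1 for the mean of fatty acid oxidation genes (0.19 against -0.09 to -0.05, 0.849).

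BRD4780 replicate 3 was placed on a scale from 0 (vehicle mean) to 1 (mean of the other treated libraries) over the 200 genes with the smallest p in the fit without it, and scored 0.389. Held-out vehicle libraries scored from 0.0199 to 0.124 and the other treated libraries from 0.827 to 1.17. Over its 200 genes BRD4780 replicate 3 thus lay away from the vehicle mean. The comparison with the vehicle scores is loose, since each held-out library had its own 200 genes and its own scale. For the vehicle scores, the treated mean also included BRD4780 replicate 3. A vehicle library with a wrong label was therefore not excluded. Over all genes tested, the other treated libraries correlated more with treated libraries (mean Spearman 0.9868 to 0.9879) than with vehicle libraries (0.9779 to 0.982). BRD4780 replicate 3 instead correlated more with vehicle libraries (0.9884) than with treated ones (0.9816). Depth is argued against, since that library holds 27.8 M counts and scored 0.314 once all libraries were thinned to the same total, against 0.808 for the next treated library. A smaller response or exposure of that mouse may underlie the score, but this was not tested. Nor was it told apart from a difference in the sampled tissue, since proximal tubule and intercalated cell markers stood apart in that library too. The number in its title occurs in no vehicle library. The same holds for BRD4780 replicate 4, which scored 1.17, and the labels name no other difference.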

How the results depend on the processing

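The thinning, the fit without BRD4780 replicates 3 and 4 and the GC and length correction were chosen after seeing the data. All 394 genes called over 8 libraries kept their direction in every alternative in which they were tested. Of the 71 called genes named by the rule, 9 (Igfn1, Gc, Atf5, Mthfd2, Kdelr3, Angptl4, Sparc, Cish and Fgf21) stayed past the threshold in every alternative that tested them. Counts stayed within 1.5 times of the 310 higher and 84 lower genes under RLE and upper-quartile normalization, other count filters, unrounded counts, a minimum log2 fold change of 0.5, thinning (289 and 93) and GC and length correction (283 and 94).

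They moved further under other tests. DESeq2 gave 864 higher and 497 lower, with 535 adjusted p-values left undefined, limma-voom 204 higher, and limma-voom with sample quality weights 1655 and 1501. Adding 1 surrogate variable gave 141 and 30, and a threshold of 0.10 gave 891 and 455. The cause was not tested, except that a looser threshold admits more genes. Without BRD4780 replicates 3 and 4 there were 1232 and 1205. Leaving out 1 library at a time gave 26 to 1647 higher and 5 to 1537 lower genes. Fewer samples lower the count by construction, which the rise without BRD4780 replicate 3 runs against.

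Each title carries a number, and 2 of these numbers occur in both groups. Deviations from the group means correlated at -0.106 and -0.367 within those pairs, and what the number marks is not given in the sources used here. As a random replicate block in limma-voom it gave 63 higher and 14 lower genes, against 204 and 70 by limma-voom without a block. The consensus correlation within the block was -0.34, so libraries with the same number were not more alike than others. As a fixed block in edgeR, which leaves 1 residual degree of freedom, the number gave 57 higher and 90 lower genes.

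Of 39 gene lists 18 passed camera with the preset correlation, 15 to 20 without 1 library, 15 after thinning, 19 without BRD4780 replicates 3 and 4 and 18 after GC and length correction, and 14 of the 18 passed in all 8 fits without 1 library. With an estimated correlation 0 passed, at a smallest adjusted p of 0.46, and by fry 0 passed, at a smallest adjusted p of 0.0599. Thinning ended the calls of the cell cycle (adjusted p = 0.14), proteasome (0.10) and glycolysis and hypoxia lists (0.0562), and the GC and length correction ended the last (0.0673) and added the circadian clock (0.0461). Without BRD4780 replicates 3 and 4 the adipocyte (median -1.03, adjusted p = 0.0953), proteasome (0.0823) and glycolysis calls (0.0587) were lost. Proximal tubule (-0.30, 6.98e-05), cholesterol synthesis (-0.22, 0.00419), macrophage (-0.71, 0.0385) and lysosome lists (-0.10, 0.0304) passed there. The median of all genes lay within 0.0358 of 0 in every setting. With 5.74 M counts, BRD4780 replicate 4 limits what can be seen of genes below about 0.523 CPM.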

Other observations

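The tests of a general ER stress response and of the vehicle 4 library were chosen only after the result was seen, the former, with its bound, after other forms of it (the sign of the list median, a t interval) had been run. Genes known to be induced by glucocorticoids were higher with BRD4780. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 110.9 ± 15.8 to 272.4 ± 38.8 CPM (SD, n = 4 per group; adjusted p = 0.00197), Tsc22d3 (GILZ, an anti-inflammatory mediator) from 89.9 ± 23.8 to 194.0 ± 32.7 CPM (SD, n = 4 per group; adjusted p = 0.0175) and Per1 2.43-fold. Fkbp5 and Tsc22d3 were singled out after their values were seen. A list of 20 other glucocorticoid-induced genes was then written before the values of that list were looked at, on the hypothesis that glucocorticoid receptor activity was higher. It was not independent of the earlier lists. Ddit4, Dusp1 and Pdk4, named here for this overlap, also belong to the ATF4, immediate early and PPARA lists tested before. Of 19 tested, 18 had a positive fold change and 4 passed the threshold, 11 when adjusted over the list alone, with a median log2 fold change of 0.52 (camera p = 1.07e-06, and p = 0.0581 with an estimated correlation). The 4 were Rgcc (1.22 ± 0.17 SE), Nfkbia (0.60 ± 0.10 SE), Errfi1 (0.52 ± 0.10 SE) and Mertk (0.47 ± 0.10 SE). Klf15 (0.05 ± 0.13 SE) and Glul (0.04 ± 0.11 SE), also on the list, gave no detectable difference. These 6 members were also named after their values were seen. These values are consistent with higher glucocorticoid signalling, from the mouse's own hormone or otherwise, but hormone levels were not measured and handling or time of day was not tested.

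BRD4780 replicate 3 followed the other treated libraries in some gene groups and not in others. Its list mean reached 66.0% of the mean of the other 3 for podocyte markers, 66.2% for endothelium, 47.2% for ATF4 targets, 39.0% for oxidative phosphorylation and 0.9% for genes higher in male kidney, and went the other way for immediate early genes (-20.9%) and ribosomal proteins (-70.3%). For ER chaperones it lay further from vehicle than the others (-0.32, against -0.27, -0.23 and 0.0043 in BRD4780 replicates 1, 2 and 4). That was 190% of their mean, which replicate 4 brought closer to vehicle. The Muc1 value of BRD4780 replicate 3, 6.65 CPM, was the lowest of all libraries. So was its mean of principal cell markers of the collecting duct (-0.92 log2 CPM relative to the vehicle mean, against -0.39 in vehicle replicate 4, the next lowest).

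For the number of changed genes, chance is argued against. Among the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 394 genes, and the highest other split gave 2.

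ATF4 targets were higher and ER chaperones lower as sets by camera with a preset correlation, with 11 of 25 and 2 of 23 members past the threshold, but not with an estimated correlation (adjusted p = 0.46 and 0.56) or by fry (0.0599 and 0.15). The choice of 1 library is argued against, since both directions held in all 8 fits without 1 library, and so is a trend with GC content and length, since 104.61% of the difference between the list medians remained once the trend was removed. A general ER stress response, in which chaperones rise with ATF4 targets, was not seen in the chaperone list, whose mean differed by -0.21 (log2). That mean lay below a rise of 0.3 (exact permutation p = 0.0286, the smallest that 70 arrangements can give). The bound was set after the t interval had been run, so this outcome was already known and decides nothing further. The ATF4 list mean differed by 1.05 (exact permutation p = 0.0286). Of 20 XBP1 targets in ER import and export, 5 were higher and 0 lower. Against no change, the chaperone difference had an exact permutation p of 0.0571, so whether chaperones fell as a set stays open, and protein levels were not measured.

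Podocyte and endothelial markers were higher as sets by camera with a preset correlation, with 4 of 13 and 4 of 16 members past the threshold, but not with an estimated correlation (adjusted p = 0.46 for both). A lower share of tubule RNA, which would raise every non-tubular type alike, is argued against because their median lay 0.87 above that of fibroblast and macrophage markers (log2, exact permutation p = 0.0286, the smallest that 70 arrangements can give). Vehicle replicate 4, the highest library for macrophage markers (0.88, log2 CPM relative to the vehicle mean), widened this difference, which was 0.51 without it (exact permutation p = 0.0571) and 0.74 to 1.01 without another library (p = 0.0286 to 0.11), above the bound of 0.3 throughout. GC content and length are argued against because at least 92.98% of each list median remained after correction. More glomeruli in the sampled slice could account for the difference and cannot be told apart from a change within these cells. Fold changes differed between podocyte markers (exact permutation p of their variance = 0.0286), but markers also differed in their shifts between vehicle libraries. The variance was 0.639 for vehicle replicate 4, a single library, against the mean of the other 3. It was 0.282 for the mean of the BRD4780 libraries against that same mean. A mean of several libraries carries less counting error than a single library, so these variances are not like for like and do not decide the question.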
